A study of Homo sapiens with 14 samples.

How the data were processed

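HepG2, a human cell line derived from a liver tumour, was transfected with miR-124 or with a negative control, and total RNA was profiled on one-colour oligonucleotide arrays. miR-124 is a small RNA that is abundant in neurons and that lowers the messenger RNA of genes with a matching site. There were 14 arrays, 7 for each transfection, taken at 4, 8, 16, 24, 32, 72 and 120 h, with 1 array for each transfection and time. Per the labels' protocols, about 10 µg of total RNA was made into biotinylated cRNA. The deposited values are log2 expression values per probe set, made with RMA per the submitters' processing notes, with version and settings not given in the sources used here. The log2 scale was taken from the values, which ran from 2.93 to 14.4 with none missing. RMA fits one level per probe set after making the arrays' distributions alike, so a change in the total amount of messenger RNA per cell cannot be seen.

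The table held 54675 probe sets, of which 62 were control probe sets. In the platform annotation given, 41091 of the others had 1 gene symbol, 1801 had several and 11721 had none listed. Gene identifiers of 41037 of the probe sets with 1 symbol matched the reference gene table, and no symbol changed. For each of 19775 genes the probe set with the highest mean over the 14 arrays was used, and 13137 genes whose mean lay above the median of all probe sets, 6.19 on the log2 scale, were tested. No depth exists for arrays, and their number limits the precision. No 2 arrays held identical values, and correlations between arrays over genes ran from 0.904 to 0.997.

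Nothing in the labels says that arrays came from separate cultures, so p-values measure only the spread between these arrays. With 1 array per transfection and time, that is the spread of the effect between times, or around the slope in the control course. It mixes change of the effect with time and spread that may be technical. Spread between replicates of a time was not measured, which also holds for the standard errors. The arrays of a time point were treated as a pair from their labels. Deviations from the group means correlated between the arrays of a pair at 0.21 to 0.48, above 0.1 in each of the 7 pairs. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. The tests were run in R 4.3.3 with limma 3.58.1 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjusted p under 0.05). The overall effect used time point as a block plus transfection, with 6 residual degrees of freedom. The effects in the early (4 and 8 h), middle (16, 24 and 32 h) and late (72 and 120 h) windows, and their differences, came from 1 fit with 4 residual degrees of freedom. That fit shares 1 estimate of the spread per gene among the windows, and changes of the ratio within the late window enter it, so the early test is a strict one. The time course in the control was a slope per doubling of time over its 7 arrays, with 5 residual degrees of freedom. Errors given with ± are standard errors from these fits unless called SD. Single time points had no replicate and were not tested.

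A total of 27 gene lists was written from general knowledge, with 532 genes of which 435 were tested. They covered reported miR-124 targets, DNA replication, mitosis, hepatocyte secreted proteins, hepatocyte metabolism, liver transcription factors, cholesterol synthesis, fatty acid synthesis, interferon response, unfolded protein response, ATF4 amino acid response, p53 targets, hypoxia response, glycolysis, ribosomal proteins, oxidative phosphorylation, adhesion and actin, extracellular matrix, neuron genes, REST and cofactors, splicing regulators, small RNA machinery, blood cell markers, fibroblast and endothelial markers, housekeeping references, apoptosis regulators and immediate early genes. Lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, with fry, and with an exact two-sided sign-flip test over the 7 pairs, whose smallest p is 0.015625. Percentiles of list medians at a time point are among 10000 random lists of the same size matched on mean expression in 20 bins. Whether the study of these arrays contributed to any of the target reports behind the first list is not known here, so that list may not be independent evidence. Lists can share genes. The target list shares ITGB1, ROCK2, RHOG and IQGAP1 with adhesion and actin, and LAMC1 and PLOD3 with extracellular matrix. It also shares PTBP1 with splicing regulators, CEBPA with liver transcription factors and the CTDSP genes with REST and cofactors.

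Genes were named by a rule. For the overall effect these were the 10 lowest and 10 highest changes among genes called with the same sign in at least 6 of 7 pairs. For each window and each difference between windows they were the 5 lowest and 5 highest called, and for the control time course the 10 steepest each way. In each list the 4 members with the largest overall change were taken, and any member of the reported targets, the REST list and the housekeeping list. Genes whose probe sets were called in opposite directions were left out, as were Y-linked genes and XIST. The groups, tests, lists, rule and other settings to try were fixed before the data were examined. These settings were no filter or a stricter filter on dim genes, the mean of all probe sets of a gene, every probe set on its own, quantile normalization again, centring each array on its median, eBayes with trend and robust, a 1.5-fold minimum, no time block, leaving out each time point, and others for the overall effect and the control time course.

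The fits were tested on simulated arrays with the real gene means, the spread of the real fits with 100 of 13137 genes changed by 1 and 100 by 2 on the log2 scale. Of the genes changed by 1 on the log2 scale, 93% were recovered for the overall effect, 90% for the early, 92% for the middle and 85% for the late window. For genes changed by 2 these shares were 99%, 98%, 98% and 97%. Unchanged genes called were 13 of 205 calls for the effect over all times, 20 of 208 early, 6 of 196 middle and 14 of 196 late. For control slopes totalling 1 over 4 doublings, 90% were recovered, and 98% for slopes totalling 2, with 5 unchanged genes among 193 calls. The simulated spread was equal at all times, which the real data did not show. Seed matches in 3′ untranslated regions and a scan of short words were planned and not run, since no transcript sequences were used here.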

Results

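The series followed gene expression in HepG2 cells after transfection with miR-124 or a negative control, and asks how the messenger RNA response to the small RNA develops from 4 to 120 h. The 7 arrays of each transfection were compared in pairs of the same time. The spread of the log2 ratio of miR-124 over control across 13137 genes was 0.15 (SD) at both 4 and 8 h, and it was 0.23 at 16 h, 0.30 at 24 h, 0.34 at 32 h, 0.61 at 72 h and 0.43 at 120 h. Genes at least 2-fold lower numbered 0 at 4 h, 8 at 8 h, 65 at 16 h, 189 at 24 h, 246 at 32 h, 778 at 72 h and 153 at 120 h. Genes at least 2-fold higher numbered 4, 0, 3, 23, 55, 506 and 303 at the same times. With 1 array per transfection and time, these counts have no test. The 4 h miR-124 array stood apart in its control probe sets, with a mean log2 signal of 11.1 for 18S ribosomal RNA against 8.70 in its control partner, and 7.86 against 6.34 for the poly-A spikes. The arms also differed in the difference between 3′ and 5′ probe sets, a measure of RNA quality, which for ACTB was higher with miR-124 in 7 of 7 pairs (mean difference 0.135 log2, exact sign-flip p = 0.015625) and for GAPDH in 6 of 7 (0.0724, exact sign-flip p = 0.03125).

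**Figure D1:**
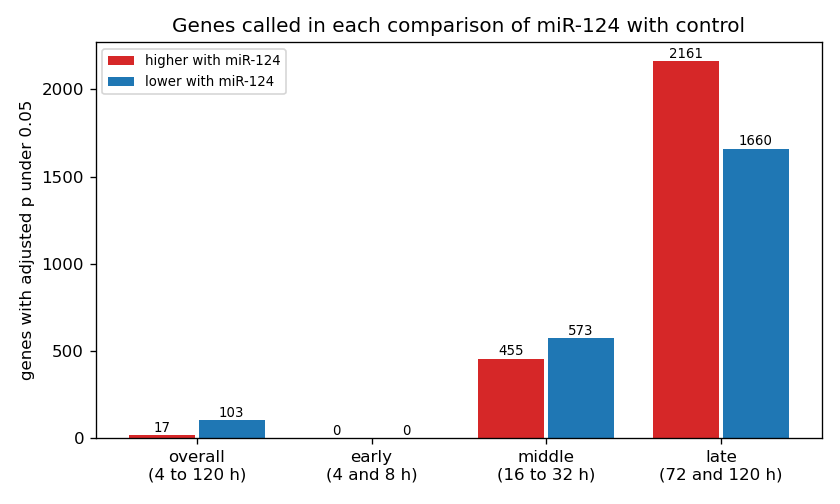
Bars show the number of genes with an adjusted p under 0.05 that were higher (red) or lower (blue) with miR-124, overall and in the early, middle and late windows. No gene was called early, 455 were higher and 573 lower in the middle window, and 2161 were higher and 1660 lower late.

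In the middle window (16, 24 and 32 h), 573 genes were lower and 455 higher with miR-124. The lowest was ATP6V0E1, a subunit of the vacuolar proton pump, at 7.31-fold below control (log2 −2.87 ± 0.36, n = 3 pairs, limma adjusted p = 0.00609). CD164, a sialomucin, was 6.61-fold lower (log2 −2.72 ± 0.35). ACAA2 and SUCLG2, both enzymes of mitochondrial metabolism, were 6.19-fold and 6.11-fold lower, and LOX, which cross-links collagen, was 5.87-fold lower. The highest were ANKRD46 at 3.53-fold (log2 1.82 ± 0.18, adjusted p = 0.00455), RRAGC, a GTPase of the amino acid sensing pathway, at 2.75-fold, the skeletal muscle actin ACTA1 at 2.58-fold, the retinol dehydrogenase RDH11 at 2.57-fold and the death receptor FAS at 2.47-fold.

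Of 28 reported miR-124 targets measured, 15 were lower in the middle window and none higher, and 20 were lower and 1 higher when adjusted over the list alone. VAMP3, a vesicle fusion protein, was 5.16-fold lower (log2 −2.37 ± 0.31), the scaffold protein IQGAP1 4.49-fold (log2 −2.17 ± 0.15), the ceramide synthase CERS2 3.69-fold and the splicing repressor PTBP1 2.40-fold (log2 −1.27 ± 0.25). The kinase CDK6 was 1.78-fold lower. LAMC1 (log2 −0.18 ± 0.08, adjusted p = 0.273) and EZH2 (log2 −0.63 ± 0.30, adjusted p = 0.289) did not pass. The list's median change was −0.64 (camera adjusted p = 1.94e-17; adjusted p = 0.376 with an estimated correlation; fry adjusted p = 0.0148). Its median ratio by time was −0.10 at 4 h, −0.15 at 8 h, −0.52 at 16 h, −0.74 at 24 h, −0.77 at 32 h, −0.87 at 72 h and −0.53 at 120 h. The median lay below that of all genes at each of the 7 times (exact sign-flip p = 0.015625, the smallest the 7 pairs can give, and 0.0844 adjusted over 27 lists, which misses the threshold). The same p came from 7 of 7 times on one side for hepatocyte secreted proteins and the ATF4 response, both below all genes, and for the interferon response and apoptosis regulators, both above.

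Other groups in the middle window changed in part. Of 17 p53 targets, 3 were higher and none lower, and 12 higher and 1 lower when adjusted over the list alone, with a list median of 0.39 (camera adjusted p = 0.00206; adjusted p = 0.875 with an estimated correlation; fry adjusted p = 0.241). FAS and SESN1, at log2 1.31 ± 0.22 and 0.88 ± 0.18, were among them. Of 18 extracellular matrix genes, 3 were lower, with a median of −0.08 (camera adjusted p = 0.0122; adjusted p = 0.875 with an estimated correlation; camera adjusted p = 0.0538 without 16 h; fry adjusted p = 0.176), among them the collagen-modifying enzymes P4HA1 (log2 −1.15 ± 0.17) and PLOD2 (log2 −1.07 ± 0.12). Of 28 adhesion and actin genes, 6 were lower and 1 higher, with ROCK1 at −1.20 ± 0.14 and CAPN2 at −1.41 ± 0.14 (camera adjusted p = 0.146, and 0.0492 without 32 h; adjusted p = 0.875 with an estimated correlation). That list also holds the reported targets ITGB1, ROCK2, RHOG and IQGAP1. Of 15 genes of the small RNA machinery, 2 were higher, the silencing scaffold TNRC6A and the exonuclease XRN1, at 0.69 ± 0.17 and 0.44 ± 0.10 (fry adjusted p = 0.0148, camera adjusted p = 0.0503, and between 0.0306 and 0.0490 without 4, 8, 32, 72 or 120 h; adjusted p = 0.622 with an estimated correlation). Among splicing regulators PTBP1 and PTBP3 were lower and PTBP2, the paralog found in neurons, was higher by 1.19 ± 0.16. None of 30 mitosis genes and none of 27 DNA replication genes was called, and the DNA replication list had a camera adjusted p of 0.226, and 0.0461 without 72 h or without 120 h (adjusted p = 0.916 with an estimated correlation).

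Of 10 REST complex genes 3 were lower, RCOR1 at −0.58 ± 0.14 and CTDSP1 and CTDSPL, which are also in the target list, at −0.76 ± 0.10 and −0.58 ± 0.11 (list median −0.12, camera adjusted p = 0.0640, and 0.0342 without 32 h; adjusted p = 0.875 with an estimated correlation; fry adjusted p = 0.302). Of 13 immediate early genes 1 was lower, KLF6 at −0.38 ± 0.07 (median −0.04, camera adjusted p = 0.113, and 0.0306 without 32 h; adjusted p = 0.916 with an estimated correlation; fry adjusted p = 0.560). Calls higher and lower were 1 and 3 of 16 for cholesterol synthesis, 1 and 3 of 18 for hypoxia, 1 and 1 of 11 for hepatocyte metabolism, 1 and 1 of 16 for the unfolded protein response, 0 and 1 of 23 for hepatocyte secreted proteins, 1 and 0 of 9 for fatty acid synthesis and 1 and 0 of 14 for neuron genes. The other 10 lists had no gene called. Adjusted over the list alone, the counts higher and lower were 4 and 6 for adhesion and actin, 3 and 0 for small RNA machinery, 1 and 4 for the REST complex, 0 and 3 for immediate early genes, 2 and 4 for hypoxia, 2 and 1 for hepatocyte metabolism, 0 and 0 for hepatocyte secreted proteins and 0 and 1 for liver transcription factors. The middle count of 1028 genes depended on single time points, with 0 called without 24 h, 12 without 32 h, 638 without 16 h, 521 without 4 h or without 8 h, and 2198 without 72 h or without 120 h. It was 1656 with every probe set. With a 1.5-fold minimum it was 458, of which 95 were higher and 363 lower. The 2198 split as 1121 higher and 1077 lower, so the larger direction turned. It also turned when the window was fitted on its own 6 arrays, an alternative chosen after seeing the data, which called 2164 genes (1090 higher, 1074 lower). Among the miR-124 arrays, those of 24 and 32 h had the largest ACTB 3′ minus 5′ differences (0.561 and 0.418). For GAPDH the 72 h array had the largest (0.301). Whether RNA quality contributed to the middle calls was not tested.

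**Figure D2:**
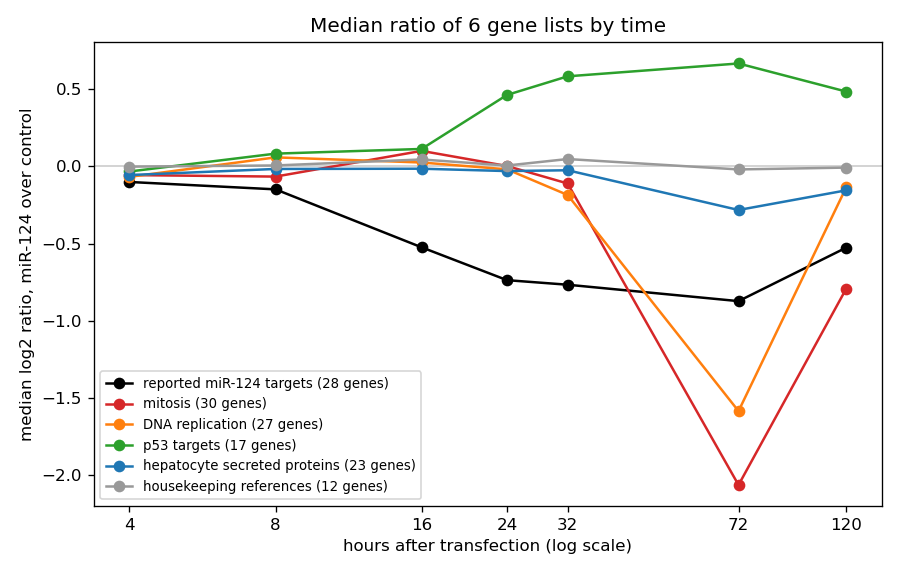
The median log2 ratio of miR-124 over control is plotted against time (log axis) for 6 gene lists, with 1 pair of arrays at each point. The reported targets lie at −0.52 by 16 h, whereas the mitosis list is at −0.11 at 32 h and −2.07 at 72 h.

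In the late window (72 and 120 h), 2161 genes were higher and 1660 lower, of 13137 tested. Counts of calls within a list are to be read against these shares. The larger direction turned with each array centred on its median (1920 higher, 1979 lower) and without 120 h (2289 higher, 2603 lower). LOX was 11.1-fold lower (log2 −3.48 ± 0.45, n = 2 pairs, limma adjusted p = 0.00144). The plasma proteins SERPINA3, CP and HP were 9.31-fold, 7.15-fold and 5.21-fold lower (SERPINA3 log2 −3.22 ± 0.09). STAR, which carries cholesterol into mitochondria, was 9.77-fold higher (log2 3.29 ± 0.19), and the transcription factor MAF 9.46-fold. The histone genes H1-2, H2BC21 and H2BC5 were 8.02-fold, 7.86-fold and 7.58-fold higher. Of the 573 genes lower in the middle window, 460 were also called lower late, where 72.4 would be shared by independent lists, and of the 455 higher genes, 391 were also called higher late against 74.8. The 2 windows use different arrays and share 1 estimate of the spread.

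All 30 mitosis genes were lower late, with a median of −1.42 (camera adjusted p = 2.86e-14; adjusted p = 0.557 with an estimated correlation; fry adjusted p = 0.0329). NCAPG was at −2.03 ± 0.48, ANLN at −1.90 ± 0.37, CDK1 at −1.81 ± 0.33 and AURKA at −1.57 ± 0.34. Their median ratio was −2.07 at 72 h and −0.79 at 120 h. The ACTB 3′ minus 5′ difference was 0.357 with miR-124 against 0.237 in the control at 72 h and 0.411 against 0.102 at 120 h, and that of GAPDH 0.301 against 0.145 and 0.199 against 0.0311. In DNA replication 11 of 27 genes were lower and none higher (16 were lower when adjusted over the list alone; median −0.81, camera adjusted p = 3.24e-06; adjusted p = 0.631 with an estimated correlation; fry adjusted p = 0.0953), with RRM2 at −1.72 ± 0.40. That list's median ratio was −1.59 at 72 h and −0.14 at 120 h, and its camera adjusted p was 0.176 without 72 h. Among p53 targets 11 of 17 were higher and none lower, with a median of 0.57 (camera adjusted p = 6.74e-05; adjusted p = 0.603 with an estimated correlation; fry adjusted p = 0.0329), and TP53I3 at 2.10 ± 0.38 and ZMAT3 at 1.18 ± 0.19. Of 15 apoptosis regulators, 6 were higher and none lower (7 were higher when adjusted over the list alone; camera adjusted p = 0.0312, and 0.115 without 72 h; adjusted p = 0.545 with an estimated correlation; fry adjusted p = 0.0118).

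Of 23 hepatocyte secreted proteins, 9 were lower late and none higher (10 were lower when adjusted over the list alone), with a median of −0.24 (camera adjusted p = 6.74e-05; adjusted p = 0.534 with an estimated correlation; fry adjusted p = 0.00480). Besides CP and HP these included C3 at −0.92 ± 0.10 and SERPINC1 at −0.96 ± 0.13. Relative to the mean of both arms at 4 h, the list's median was −0.05 at 72 h and 0.08 at 120 h with miR-124 and 0.21 and 0.39 in the control. Of 11 genes of hepatocyte metabolism, 3 were higher and 1 lower, with CYP3A5 at 1.93 ± 0.15, CYP4F3 at 1.52 ± 0.12 and CPS1 at −0.42 ± 0.11 (camera adjusted p = 0.164, and 0.00554 without 72 h; adjusted p = 0.631 with an estimated correlation; fry adjusted p = 0.0329). Of 19 ATF4 response genes, 12 were lower and 1 higher, with a median of −0.60 (camera adjusted p = 0.000409; adjusted p = 0.534 with an estimated correlation; fry adjusted p = 0.00480), and the cysteine-forming enzyme CTH at −1.80 ± 0.13. Relative to 4 h this list's median was −0.49 at 72 h and −0.13 at 120 h with miR-124 and −0.04 and 0.58 in the control. Of 21 ribosomal protein genes, 8 were lower, with a median of −0.20 (camera adjusted p = 0.00059; adjusted p = 0.545 with an estimated correlation; fry adjusted p = 0.00483), and RPL30 and RPL19 at −1.12 ± 0.20 and −1.11 ± 0.21. In the unfolded protein response 4 of 16 genes were lower and 1 higher (camera adjusted p = 0.0159, and 0.826 without 72 h; adjusted p = 0.631 with an estimated correlation; fry adjusted p = 0.142), with XBP1 at −0.81 ± 0.19 and SEL1L at 0.48 ± 0.09.

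The reported targets were low in the late window too, with 19 of 28 lower and 1, RDH10, higher at 0.42 ± 0.09 (median −0.75; camera adjusted p = 2.36e-06; adjusted p = 0.534 with an estimated correlation; fry adjusted p = 0.0125). Adjusted over the list alone, 20 were lower and 2 higher. TEAD1 was at −1.51 ± 0.13 in the middle window and −0.58 ± 0.17 late. Of 10 REST complex genes, 4 were lower, which were RCOR1, CTDSP1, CTDSP2 and CTDSPL, the last at −0.99 ± 0.13 (camera adjusted p = 0.00458, and 0.0788 without 72 h; adjusted p = 0.557 with an estimated correlation; fry adjusted p = 0.0329). 3 of the 4, the CTDSP genes, are also in the target list. REST itself was at −0.24 ± 0.11 (adjusted p = 0.129). Of 14 neuron genes, PTBP2 (2.40 ± 0.19) and ENO2 (1.24 ± 0.28) were higher and none lower, with a list median of −0.05 and a mean of 0.19 (camera adjusted p = 0.974).

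The remaining lists had few or mixed calls late. Calls higher and lower were 6 and 1 of 15 for the interferon response, 4 and 5 of 18 for hypoxia, 4 and 3 of 16 for glycolysis, and 8 and 7 of 28 for adhesion and actin. They were 2 and 6 of 18 for extracellular matrix, 0 and 4 of 16 for cholesterol synthesis, 1 and 0 of 9 for fatty acid synthesis, 0 and 1 of 8 for liver transcription factors, and 0 and 2 of 19 for oxidative phosphorylation. They were 1 and 3 of 19 for splicing regulators, 4 and 2 of 15 for small RNA machinery, and 1 and 2 of 13 for immediate early genes. Among markers of other cells, 1 of 8 blood markers, CD3D at 1.44 ± 0.25, and 2 of 11 fibroblast and endothelial markers, ACTA2 at 1.07 ± 0.17 and PECAM1 at 0.46 ± 0.11, were higher. These shares are close to that of all genes, 2161 higher of 13137. Of 12 housekeeping genes 2 were lower, TFRC and PGK1, the latter at −0.27. Adjusted over the list alone, the counts higher and lower were 5 and 5 for hypoxia, 4 and 4 for glycolysis, 10 and 7 for adhesion and actin, 0 and 1 for oxidative phosphorylation and 0 and 1 for housekeeping, and unchanged for the other lists of this paragraph. The median and the mean had opposite signs for hypoxia (0.19 and −0.17), glycolysis (−0.06 and 0.14), adhesion and actin (0.02 and −0.01), extracellular matrix (0.04 and −0.33), blood markers (−0.13 and 0.06), fibroblast and endothelial markers (−0.11 and 0.05) and housekeeping genes (0.09 and −0.03). The interferon list had a median of 0.26 (fry adjusted p = 0.00480, camera adjusted p = 0.0636; adjusted p = 0.534 with an estimated correlation). Of the lists of this paragraph fry also called small RNA machinery higher (adjusted p = 0.0329) and extracellular matrix (adjusted p = 0.0427) and housekeeping genes (adjusted p = 0.0481) lower. Of these lists camera called none in the full set of times, and without 72 h it called hypoxia (adjusted p = 0.00554, median −0.34) and extracellular matrix (adjusted p = 0.0454), and without 120 h hypoxia the other way (adjusted p = 0.0209, median 0.72), cholesterol synthesis (adjusted p = 0.0112) and splicing regulators (adjusted p = 0.000179). With no time left out, the late adjusted p with an estimated correlation was 0.631 for small RNA machinery and cholesterol synthesis, 0.731 for extracellular matrix, 0.933 for housekeeping genes, 0.989 for hypoxia and 0.891 for splicing regulators. The late count of 3821 was 7031 with every probe set and 2062 with a 1.5-fold minimum. It used the spread shared by the windows, and 469 genes (340 higher, 129 lower) were called when that window was fitted on its own 4 arrays, an alternative chosen after seeing the data.

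**Figure D3:**
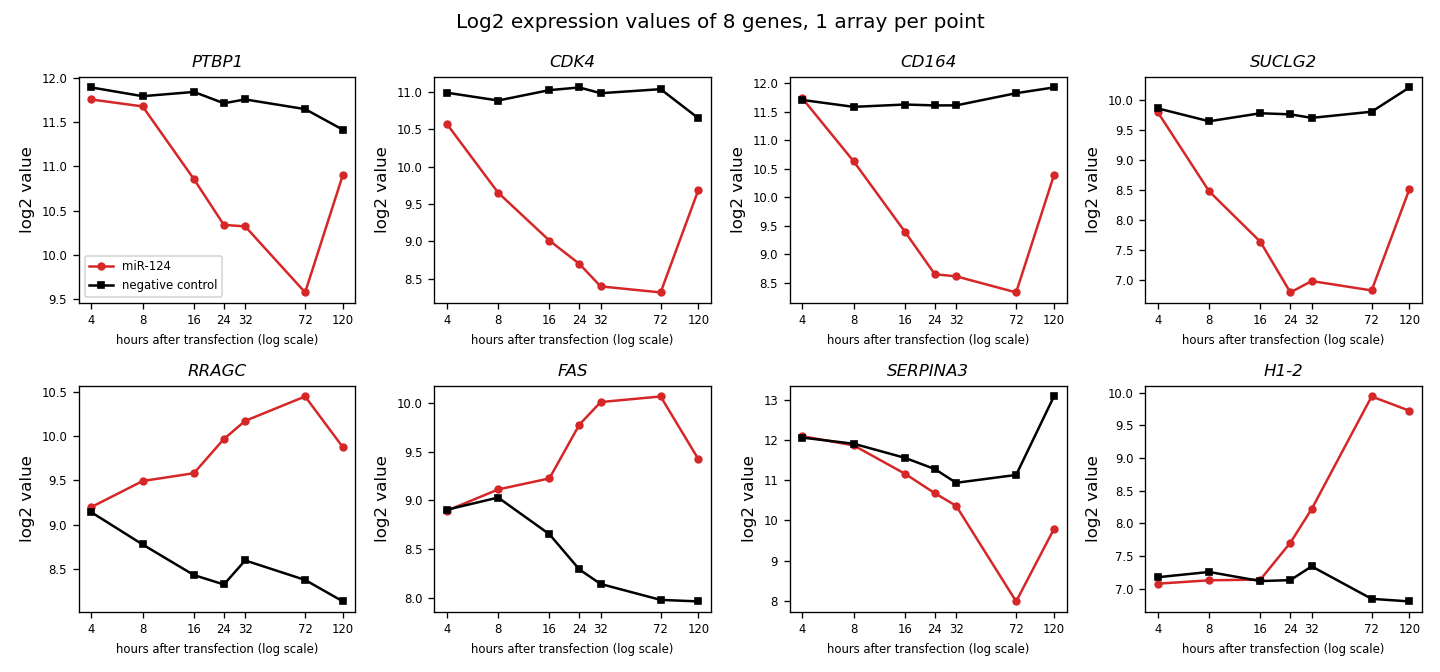
Log2 values of 8 genes are plotted against time (log axis) in miR-124 (red) and control (black) cells, with 1 array per point and a separate vertical scale for each gene. CDK4, CD164 and SUCLG2 lie below control at 8 h and later, and their miR-124 values are higher at 120 h than at 72 h.

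In the early window (4 and 8 h) limma called 0 genes, with 163 at an unadjusted p under 0.05 where 656.85 would be expected by chance, and fitted on its 4 arrays alone it also called 0, with 316 unadjusted. The same test was run on simulated arrays with an equal spread at all times. There, 100 genes were changed by 1 and 100 by 2 on the log2 scale at both 4 and 8 h. Of the changes of 1, 90% were recovered. Fewer changed genes, or changes at 8 h only, were not simulated, so this share need not hold for them. The 8 genes at least 2-fold lower at 8 h, chosen after their values were seen, included SLC40A1 (log2 ratio −1.25), CDK4 (−1.23), COBLL1 (−1.20), SUCLG2 (−1.17) and ACAA2 (−1.01). The reported targets had an early median of −0.15 (camera adjusted p = 1.67e-05; adjusted p = 0.922 with an estimated correlation; fry adjusted p = 0.995). Camera also called adhesion and actin (median −0.08), extracellular matrix (−0.13) and REST and cofactors (−0.10) lower and fibroblast and endothelial markers (0.08) higher, each at adjusted p = 0.922 with an estimated correlation and fry adjusted p = 0.995. The 4 h miR-124 array, with its high 18S and spike signals, is 1 of the 2 behind these early values.

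Averaged over all 7 times, 103 genes were lower and 17 higher. SUCLG2 was 3.90-fold lower (log2 −1.96 ± 0.34, limma adjusted p = 0.0499, lower in 7 of 7 pairs), ACAA2 3.78-fold, the cell-cycle kinase CDK4 3.38-fold and the centromere protein CENPQ 3.07-fold. MIGA1, IQGAP1, RPIA, GAS2L1, SMPDL3A and NEK6 followed at 2.99-fold to 2.40-fold. RRAGC was highest at 2.43-fold (log2 1.28 ± 0.22, higher in 7 of 7 pairs), followed by TAPT1, TPRG1L, ZCCHC10, TDG, PDZD8, NFAT5, FAM217B, SP4 and ACBD5 at 1.77-fold to 1.45-fold. Of the reported targets 4 of 28 were lower and none higher (22 lower and 1 higher when adjusted over the list alone; median −0.54, camera adjusted p = 4.87e-12; adjusted p = 0.641 with an estimated correlation; fry adjusted p = 0.0552). Camera also called mitosis (median −0.44, adjusted p = 4.64e-06), DNA replication (−0.24, 0.000607), the REST complex (−0.13, 0.00391), hepatocyte secreted proteins (−0.08, 0.00609), ribosomal proteins (−0.06, 0.0105) and extracellular matrix (−0.07, 0.0448) lower, and p53 targets (0.32, 0.00101) and apoptosis regulators (0.15, 0.0303) higher. No gene of these 8 lists was called, each had an adjusted p = 0.641 with an estimated correlation, and fry called none. Of other lists, 3 adhesion and actin genes, RHOG, ROCK1 and IQGAP1, and HMGCS1 of cholesterol synthesis were lower. RHOG and IQGAP1 are also in the target list. Adjusted over the list alone, 13 p53 targets and 4 apoptosis regulators were higher, and 2 p53 targets, 4 REST complex, 4 extracellular matrix, 6 adhesion and actin and 3 cholesterol synthesis genes lower, with 1 of cholesterol synthesis higher. Glycolysis, small RNA machinery and fibroblast and endothelial markers had 1 higher each and hepatocyte metabolism 1 lower. Such counts higher and lower were 2 and 5 for hypoxia, 1 and 2 for splicing regulators, 0 and 2 for immediate early genes and 0 and 1 for liver transcription factors. Single times ended the call of ribosomal proteins (adjusted p = 0.0948 without 120 h) and of extracellular matrix (0.0801 to 0.112 without 4, 16 or 24 h). Others gave calls to cholesterol synthesis, the unfolded protein response, the ATF4 response, splicing regulators and small RNA machinery, at adjusted p = 0.0242 to 0.0466. The adjusted p-values lay just under the threshold, the smallest being 0.0435, with 3413 genes at an unadjusted p under 0.05. The count of 120 was 974 without 4 h (392 higher, 582 lower) and 692 without 8 h (254 and 438), and 0 without 16, 24, 32, 72 or 120 h. It was 0 after quantile normalization again or with the mean of all probe sets, 1 after centring or with no filter, 72 with a 1.5-fold minimum, 328 with no time block (86 higher, 242 lower) and 454 with every probe set. Without the early window it was 1854, of which 1010 were higher and 844 lower.

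The effect differed between windows for 1521 genes late against early (1088 higher late, 433 lower) and for 624 genes late against middle (422 and 202). Centring each array on its median gave 859 higher and 706 lower for the former and 376 and 277 for the latter, and quantile normalization again gave 963 and 615 for the former. For middle against early limma called 0, with 1252 at an unadjusted p under 0.05. Without 72 h or without 120 h it called 264, of which 81 were higher and 183 lower. For this difference camera called the reported targets lower (median −0.54, adjusted p = 6.52e-13; adjusted p = 0.620 with an estimated correlation) and p53 targets higher (0.41, adjusted p = 5.12e-05; adjusted p = 0.990 with an estimated correlation), and fry called neither. From early to late the change was largest for STAR (3.45 ± 0.26), MAF (3.44 ± 0.35) and H1-2 (3.12 ± 0.25) upwards and for LOX (−3.23 ± 0.64), SERPINA3 (−3.22 ± 0.13) and CP (−2.73 ± 0.30) downwards. Against the middle window the ratio of VNN1, a pantetheinase, was higher by 2.45 ± 0.12 and that of HAL, which degrades histidine, lower (−2.10 ± 0.35), with NUF2 and CDK1 at −2.25 ± 0.39 and −1.93 ± 0.42. The late against early count was 2581 with every probe set, and the late against middle count 384 with a stricter filter. The former was 203 without 4 h (173 higher, 30 lower), 259 without 8 h (217 and 42), 732 without 24 h and 3719 without 120 h, the last with 1772 higher and 1947 lower. The late against middle count was 297 without 4 h or 8 h, 148 without 16 h, 78 without 24 h (61 higher, 17 lower), 245 without 32 h, 1175 without 72 h and 2369 without 120 h, the last with 1033 higher and 1336 lower.

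In control cells 355 genes rose and 720 fell with time, a split that was 475 and 506 with each array centred on its median. The steepest rises per doubling of time were those of HAL (0.61 ± 0.12, adjusted p = 0.0255), ANGPTL8 (0.49 ± 0.12), SLCO4C1 (0.47 ± 0.09), HMGCS1 (0.46 ± 0.07) and MSMO1 (0.41 ± 0.03). The steepest falls were those of NPNT (−0.66 ± 0.15, adjusted p = 0.0386), ACTA1 (−0.43 ± 0.09), TNFRSF11A (−0.39 ± 0.04), MAP3K8 (−0.39 ± 0.06) and HMOX1 (−0.38 ± 0.05). Of 16 cholesterol synthesis genes, 12 rose and none fell (median slope 0.29, camera adjusted p = 6.62e-13; adjusted p = 0.528 with an estimated correlation; fry adjusted p = 0.0347). Of 30 mitosis genes, 19 fell and none rose (median slope −0.15, camera adjusted p = 2.69e-16; adjusted p = 0.528 with an estimated correlation; fry adjusted p = 0.0347). Of 27 DNA replication genes, 10 fell (camera adjusted p = 5.74e-10; adjusted p = 0.528 with an estimated correlation; fry adjusted p = 0.0637). Adjusted over the list alone, these counts were 15, 29 and 18. Of 23 hepatocyte secreted proteins 2 rose (median slope 0.07, camera adjusted p = 3.64e-06; fry adjusted p = 0.129). Of 19 splicing regulators 4 fell, and 12 adjusted over the list alone (camera adjusted p = 4.46e-06; fry adjusted p = 0.0547). Of 9 fatty acid synthesis genes 1 rose, and 6 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.00539; fry adjusted p = 0.132). These 3 lists each had an adjusted p = 0.528 with an estimated correlation. Of 19 ATF4 response genes 4 rose (camera adjusted p = 0.0495; adjusted p = 0.670 with an estimated correlation; fry adjusted p = 0.221). Of 8 blood cell markers none was called (camera adjusted p = 0.0495; adjusted p = 0.528 with an estimated correlation; fry adjusted p = 0.129). Of 17 p53 targets 5 fell, and 7 adjusted over the list alone (fry adjusted p = 0.0347, camera adjusted p = 0.0599; adjusted p = 0.528 with an estimated correlation). The count of 1075 genes was 475 without 4 h (267 rose and 208 fell, the other way round), 229 without 8 h, 486 without 16 h, 425 without 24 h, 609 without 72 h and 575 without 120 h. It was 2857 on a linear scale of hours, 3655 with all 14 arrays (1714 rose, 1941 fell), 1826 with every probe set, 2 with a 1.5-fold minimum per doubling, and 665 with 1.5-fold over the whole course, an alternative chosen after seeing the data.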

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

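Of the tests reported in this part, those on the mitosis genes and on the timing of the histone genes were chosen after the result was seen. Samples far from the others were sought in 45 sets of 7 values, and 11 were found. For independent draws chance gives about 1 in 20. That rate need not hold here, since the 7 values of a set are from different times and a late response can also be flagged. Among the 7 miR-124 arrays the 4 h array was highest in poly-A spikes (7.858, next 6.359), hybridization spikes (9.744, next 9.494) and 18S ribosomal RNA (11.05, next 8.282), and the 24 h array in the ACTB 3′ minus 5′ difference (0.5611, next 0.4178). Among list medians of the log2 ratio, 72 h was lowest for DNA replication (−1.587, next −0.1851), mitosis (−2.066, next −0.7936), the unfolded protein response (−0.8475, next −0.0992), REST and cofactors (−0.4839, next −0.1798) and splicing regulators (−0.591, next −0.062). At 120 h hepatocyte metabolism was highest (0.3397, next 0.0471) and fibroblast and endothelial markers lowest (−0.1437, next −0.0114).

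The effect of miR-124 differed by a test of the difference for 1521 genes between the late and early windows and for 624 between the late and middle windows. Lists that differed by both camera with a preset correlation and fry were hepatocyte secreted proteins, with a median difference of −0.194 late against early and −0.2037 late against middle, the ATF4 response (−0.5872 and −0.5042), ribosomal proteins (−0.1908 and −0.1956) and, late against middle, the interferon response (0.1644). With an estimated correlation camera called none of these. Probe sets with no or several listed genes were used only in the setting with every probe set. Out of 4431 of them, 66 were called for the effect over all times, 181 in the middle and 873 in the late window.

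Mitosis genes lay further below control at 72 h (median ratio −2.07) than at 120 h (−0.79). The control arm's own fall between these times made up 0.2073 of the mean change (bootstrap interval over 30 genes 0.1603 to 0.2553), which describes these arrays and leaves a fall of the control arm open, since intervals over genes do not cover the spread between arrays and each arm has 1 array per time. RNA quality of the 72 h array cannot be told apart, since the ACTB difference was higher with miR-124 in 7 of 7 pairs, and the 24 h array, at a mitosis median of 0.002814 (−0.07448 to 0.05099), had a larger ACTB 3′ minus 5′ difference (0.561 against 0.357) but a smaller GAPDH one (0.286 against 0.301) and is 1 array. The reported targets moved back by a median of 0.4482 from 72 to 120 h (0.2007 to 0.6902 over 28 genes), as a fading action of miR-124 could give, a hypothesis from the same data. A peculiarity of the 72 h array could move the targets the same way, which was not tested. With 1 array per arm and time these cannot be told apart, and an outgrowth of cells that took up less miR-124 was not tested.

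The 455 genes called higher in the middle window could reflect a fall in control cells, as FAS and RRAGC fell with time in the control (−0.24 ± 0.03 and −0.17 ± 0.03 per doubling). Over all 455, the control arm made up 0.1005 of the mean difference from the level at 4 and 8 h (0.05669 to 0.1423 over genes, and 0.0222 to 0.167 from the spread between control arrays with the miR-124 arm held fixed, an interval chosen after the result was seen), which argues against this as the main part for the set. The mean change was 0.44 in the miR-124 arm and −0.05 in the control arm, and the control arm was below the mean level of both arms at 4 and 8 h for 265 of them. In such a mean, rises and falls of the control offset each other, and single genes differed from it. From 4 to 24 h FAS went from 8.90 to 8.29 in the control and from 8.89 to 9.78 with miR-124. RRAGC went from 9.14 to 8.32 in the control and from 9.20 to 9.97 with miR-124. A biological explanation for the difference was not tested.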

How the results depend on the processing

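Windows fitted on their own arrays and the 1.5-fold minimum over the whole control course were chosen after the results were seen. The count over all times, 120 genes, was 1 with no filter on dim genes, 0 with the mean of all probe sets, 454 with every probe set tested, 0 after quantile normalization again, 1 after centring, 328 (242 lower, 73.8%, against 85.8%) with no replicate block, 72 with a 1.5-fold minimum and 1854 (844 lower, 45.5%) without the early window. Leaving out a time point gave 0 to 974. The early count of 0 was the same under each alternative. The middle count of 1028 was 1656 with every probe set and 458 with a 1.5-fold minimum, and 0 to 2198 without a time point. The late count of 3821 was 7031 with every probe set, 2062 with a 1.5-fold minimum, and 2861 to 4892 without a time point. Late against early (1521) was 2581 with every probe set and 203 to 3719 without a time point, late against middle (624) was 384 with the stricter filter and 78 to 2369, and middle against early (0) was 0 to 264, the 264 without 72 h or without 120 h. The control time course (1075) was 1826 with every probe set, 2857 on a linear scale, 3655 with all 14 arrays, 2 with a 1.5-fold minimum per doubling and 229 to 1112 without a time point. Windows fitted on their own arrays gave 2164 middle (1028 shared with the original calls) and 469 late (468 shared), and a 1.5-fold minimum over the whole control course gave 665. Centring moved the share of lower genes from 43.4% to 50.8% in the late window, from 28.5% to 45.1% late against early, from 32.4% to 42.4% late against middle and from 67.0% to 51.6% in the control course, and quantile normalization from 28.5% to 39.0% late against early. The larger direction also turned without 120 h in the late window (2289 higher, 2603 lower) and in both late differences, without 72 h or 120 h in the middle window (1121 and 1077), with the middle window on its own arrays (1090 and 1074) and without 4 h in the control course (267 and 208). Where a time point left out leaves a window with 1 pair, that pair is assumed to vary like the others. Fewer arrays or more probe sets account for part of these moves by construction, and otherwise the cause was not tested. Taking time out of the fit moved no other count of genes called between the arms by over 1.5 times. It was not run for the control time course or for the lists.

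Lists called by camera numbered 9 over all times, 3 middle and 10 late, and 0 in each with an estimated correlation. The middle number was 7 with no filter and 2 to 7 without a time point. The hypoxia list, not called late (median 0.19), was called with a median of −0.34 without 72 h and of 0.72, in the other direction, without 120 h. Relative to 4 h, its median with miR-124 was 0.197 at 72 h and 0.145 at 120 h. In the control it was −0.161 and 0.666, so in these arrays the turn lay mainly in the control arm. Each arm has 1 array per time. Of other list results, 283 stayed on their side of the threshold, 28 lost and 13 gained the call under other settings, and 533, 9 and 24 without a time point. Of results for named genes these numbers were 1466, 121 and 65, and 1253, 199 and 60, and none changed sign with a call. For the effect over all times, 131 of 156 had no call to lose. The other 25 lost theirs without 16, 24, 32, 72 or 120 h, after quantile normalization again, after centring and with no filter. None did without 4 or 8 h. The 10 of the middle window lost theirs without 24 or 32 h. All 10 kept them without 16, 72 or 120 h, and 9 did without 4 or 8 h. The 10 of the late window kept theirs without 4, 8, 16, 24 or 32 h. Rescaling turned the sign of 2 list medians near 0, mitosis in the middle window (−0.01 to 0.01) and adhesion and actin late (0.02 to −0.02). Seed sites, the heptamer scan and their alternatives were not run for lack of sequences. Dim genes limit what can be seen, since probe sets near background compress differences.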

Other observations

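The histone lists, their tests without the genes that prompted them and the tests of histone timing were chosen after the result was seen. The group was defined after H1-2, H2BC5 and H2BC21 appeared among the highest late genes. Of 18 genes of the replication-dependent clusters measured, 9 were higher late and none lower, with a median of 0.36 (camera p = 7.5e-07, and p = 0.0189 with an estimated correlation, not adjusted and on genes that include those that prompted the list). Without these 3, 6 of 15 were higher and none lower, with a median of 0.24 (camera p = 0.000262, and p = 0.0176 with an estimated correlation, not adjusted). Of 8 replication-independent histone genes, none was higher and 1 lower, with a median of 0.07. The median ratio of the 18 genes was 0.06 at 16 h, 0.19 at 24 h, 0.15 at 32 h, 0.37 at 72 h and 0.51 at 120 h.

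Among the explanations, probe sets shared by similar histone genes cannot be told apart from a change in the genes. The 10 probe sets with a plain suffix had a median late effect of 0.1298 (bootstrap interval −0.004365 to 1.308) with 3 called higher, against 1.11 and 7 called higher among 9 shared ones, and the interval is too wide to decide. A rise that follows the fall of mitosis genes stays open too. At 24 h the histone median was 0.1884 (0.09183 to 0.3205) and the mitosis median 0.002814 (−0.07448 to 0.05099), which is 1 pair of arrays, and the larger late histone difference came with that of the mitosis genes. That part of the histone change may come before the mitosis change is a hypothesis.

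Exchanging the arms within time points gave 64 splits, of which 1, the real one, called as many as 120 genes. The highest of the others called 0. That makes chance unlikely for this count at the settings used and does not exclude it. There are only 64 splits, and an exchange turns a difference shared by the pairs into spread, which lowers the other counts. The count lay at the threshold, with a smallest adjusted p of 0.0435, and it was 0 after quantile normalization again, 0 with the mean of all probe sets, 1 after centring and 0 without 16, 24, 32, 72 or 120 h. Another 36 splits that parted fewer pairs, drawn at random, called at most 0. For the middle window the 4 splits within its 3 pairs are too few for a share under 0.05, with 1 split reaching the real 1028 and 0 as the highest other.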
